A study of Arabidopsis thaliana with 48 samples.

How the data were processed

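Rosette leaves of Arabidopsis Col-0 (WT) and of a line in which a mutation of MTA, the catalytic subunit of the mRNA adenosine methylase, is complemented by MTA under the embryo-active ABI3 promoter (mta below) were sampled from watered control plants and from plants that went 12 days without water. Each of the 4 groups was measured with 4 assays and 3 libraries per assay, 48 libraries in all. The assays were mRNA-seq, immunoprecipitation of fragmented poly(A) RNA with an antibody against N6-methyladenosine (m6A), sequencing of polysomal RNA pooled from sucrose gradient fractions, and GMUCT, which captures RNA with a free 5′ monophosphate and so reads uncapped, decaying transcripts. The mRNA libraries are the share of the fragmented RNA kept back as input of the immunoprecipitation. The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values measure the spread between these samples. Correlations of the residuals of libraries with the same replicate number lay between -0.163 and 0.156, with a mean of 0.0248 against -0.0121 for other pairs where mRNA and GMUCT libraries of a group were compared. The labels name no pairs, so no pairing was used, and a replicate block was run as an alternative.

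For 36 libraries the deposited values are raw counts per gene. Per the file headers they were made with featureCounts 2.0.1 or 2.0.3 on whole gene spans of TAIR10 from start to end, introns included. Per the submitters' processing notes FastQC, Trim Galore, cutadapt, STAR, bedtools and SAMtools were used, with roles and versions not given in the sources used here. In the polysomal tables between 95.6% and 96.7% of the low counts were even, against 44.0% to 46.4% in the other assays, as when both reads of a pair are counted, so polysomal totals overstate the number of fragments. The GMUCT reads were counted without regard to strand per the file headers. For 12 libraries the authors deposited narrowPeak lists per library and strand, named as MACS2 output, with a fold enrichment (a ratio) at each summit and with the −log10 p and −log10 q of each peak. The library used as the background of the peak calling was not given in the sources used here. A separate table per mRNA library holds counts of noncoding RNAs.

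Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood F test was made on a model with 1 mean per group. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a contrast, with a threshold of 0.05. The 5 contrasts tested in the mRNA libraries were drought against control in WT, drought against control in mta, mta against WT in control, mta against WT in drought, and the difference of the drought effects (mta minus WT), which is the interaction of genotype and watering. The same contrasts were tested on the uncapped share, defined as GMUCT minus mRNA on the log2 scale, in 1 model over the 24 libraries of both assays, and on polysome association, defined as polysomal minus mRNA. Both measures hold the same mRNA libraries as their denominator, so a change of the mRNA libraries alone moves both. The noncoding RNAs were tested with the library sizes and scaling factors of the gene tables. Values are log2 fold changes ± SE from these fits with 3 libraries per group and assay.

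Gene lists were fixed before the data were examined, as were the tests, the thresholds, most alternatives and the rule for naming genes. They cover m6A writers, erasers and readers, drought and abscisic acid (ABA) induced proteins, ABA synthesis, breakdown and signalling, proline and raffinose metabolism, photosynthesis, cytosolic ribosomal proteins, heat shock proteins and factors, reactive oxygen handling, senescence and autophagy, the salicylate and immune response, the jasmonate response, aquaporins, cell wall and expansion, trichome formation, guard cells, vascular tissue, the circadian clock and mRNA decay, plus markers of flower and meristem, seed and root as tissues other than the leaf. Of 350 members written down, 321 were paired with their symbol in the annotation and 22 had none there. The 7 given another symbol there were dropped, among them the writers MTB and VIR. Lists were tested with limma 3.58.1 camera on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Genes named in the text are MTA, up to 3 members of each list past the threshold with the largest change, and the 5 rising and 5 falling genes with the largest change among those with a mean of at least 2 on the log2 CPM scale; for the mRNA contrasts these also had no overlap between the libraries of the groups compared. Some were left out for length.

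Peaks were merged by strand in Python 3.11.15, and a region counted as present in a group when peaks of at least 2 of the 3 libraries held it. A WT region was called absent in mta when no peak of any mta library of that watering regime overlapped it by a base. The reverse count was made with the same rules as a background of the peak calling, and it was not made for the gene lists. The position of a peak of a library is that of its summit along the gene span, split into 10 equal parts. The position of a merged region is that of its middle. Genes with every WT region absent in mta were set against genes with a WT region that was kept, with camera in each of the 3 gene measures and both regimes, 6 tests. In simulations of this comparison for mRNA in drought, with 1773 of 10284 genes as lost and genes independent, 0 of 20 were called without a shift and 20 of 20 with a shift of 0.1 on the log2 scale. The merging was checked on 50 simulated peak sets.

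With changes simulated on the real spread, the mRNA test of genotype in drought called 25.4% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 100% of those changed by 2, and 8.67% of its calls were false. For the uncapped share the same shares were 0%, 41.8% and 72.7%, and for polysome association 11.9%, 58.2% and 86.4%. For the difference of the drought effects a change of 1 was called in 59.7% of genes in mRNA, 19.4% in the uncapped share and 37.3% in polysome association. A fold against a group in which the 3 libraries held 0 counts is given as a bound against a floor of 3 counts over the group, and such floors cover counting error only.

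The alternatives were median-of-ratios scaling, no low-count filter, nuclear genes alone, a minimum 2-fold change, DESeq2 1.42.0, limma voom with sample weights, fits of the compared groups alone, a replicate block, each library left out in turn and, for peaks, other rules of support, overlap and threshold and the same number of peaks (7746) in every library. Removal of each library's trend of counts along the gene span (lowess, span 0.3), the halving of polysomal counts, and the rescaled and left-out versions of the list tests were added after the data were seen. Exons, untranslated regions and sequence motifs were not analysed here, since no genome sequence was at hand.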

Results

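The series holds 48 libraries from rosette leaves, 3 for each combination of 2 genotypes (WT and mta), 2 watering regimes (control and 12 days of drought) and 4 assays (mRNA-seq, m6A immunoprecipitation, polysomal RNA-seq and GMUCT). Total counts lay between 1504013 and 5503037 in the mRNA libraries, between 35833742 and 43032763 in the polysomal libraries and between 1313457 and 12421168 in the GMUCT libraries. The m6A libraries came as peak lists of 7746 to 12228 peaks, whose sequencing depth is unknown. In the mRNA libraries the first principal component, which set drought apart from control, held 70.8% of the variance. WT control replicate 3 was the shallowest mRNA library and had 11.7% of its counts on plastid genes, against 1.93% to 4.36% in the other mRNA libraries.

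The line was first checked for its MTA transcript in leaves. MTA (AT4G10760) stood at 18.3 ± 0.599 CPM (counts relative to the normalised library total) in WT control leaves and 8.04 ± 1.49 in mta control leaves (SD, n = 3), and at 23.4 ± 3.88 and 9.56 ± 1.2 in drought. The log2 fold change in mta was -1.16 ± 0.19 in control (adjusted p = 9.6e-05) and -1.28 ± 0.18 in drought (adjusted p = 3.07e-06). The polysomal libraries held 15.5 CPM of MTA in WT control and 5.22 in mta control, and the GMUCT libraries 14.5 and 5.73. Among the 6 measured m6A writers, 1 rose and 1, MTA, fell in mta in control, and 1 rose and 4 fell in drought.

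What drought did to leaf mRNA in WT was the first question. Transcripts of protective, ABA-induced proteins rose by up to 12.69 on the log2 scale, and those for photosynthesis, water channels and the jasmonate response fell. Of 17666 genes tested, 12000 changed, 5762 upward and 6238 downward (6475 and 5949 with the span trend removed), and 6787 changed at least 2-fold. Of the 21 drought and ABA induced proteins, 20 rose and 1 fell, with a median log2 fold change of 4.21 (adjusted p = 9.56e-16, and adjusted p = 0.0223 with an estimated correlation). LEA7 (AT1G52690), a late embryogenesis abundant protein, rose by 12.69 ± 0.26, LTI65 (AT5G52300), also known as RD29B, by 10.38 ± 0.17, and the dehydrin RAB18 (AT5G66400) by 10.04 ± 0.13. Of 35 genes of ABA synthesis, breakdown and signalling, 24 rose and 7 fell (median 1.18, adjusted p = 5.09e-05, and adjusted p = 0.0132 with an estimated correlation). The phosphatase HAI1 (AT5G59220), which is induced by ABA and restrains its signalling, rose by 4.87 ± 0.11. Its relative HAI3 (AT2G29380) was at least 223-fold higher, and the ABA receptor PYL4 (AT2G38310) had a log2 fold change of -5.30 ± 0.28. In proline and raffinose metabolism 7 of 10 genes rose and 3 fell (adjusted p = 0.00154, and adjusted p = 0.0899 with an estimated correlation). The proline synthesis enzymes P5CS1 (AT2G39800) and P5CS2 (AT3G55610) rose by 4.70 ± 0.09 and 4.11 ± 0.09. Of 17 heat shock genes 11 rose and 3 fell, with a median of 2.29 (adjusted p = 0.00279, and adjusted p = 0.138 with an estimated correlation), and the plastid chaperone HSP21 (AT4G27670) was at least 69.7-fold higher.

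All 31 photosynthesis genes fell in WT in drought, with a median log2 fold change of -2.46 (adjusted p = 9.79e-24, and adjusted p = 0.0132 with an estimated correlation). The Rubisco small subunit RBCS2B (AT5G38420) changed by -6.14 ± 0.13, and the light-harvesting proteins LHCB2.3 (AT3G27690) and LHCB6 (AT1G15820) by -5.55 ± 0.11 and -4.38 ± 0.12. Of 13 jasmonate genes 12 fell and 1 rose (median -1.92, adjusted p = 2.39e-06, and adjusted p = 0.0132 with an estimated correlation). Among them the lipoxygenase LOX2 (AT3G45140) and the defensin PDF1.2 (AT5G44420) changed by -5.14 ± 0.14 and -5.14 ± 0.15. Of 21 salicylate and immune genes 14 fell and 3 rose, or 14 and 4 adjusted over the list alone (adjusted p = 0.00279, and adjusted p = 0.0899 with an estimated correlation). PAD4 (AT3G52430), which is needed for basal defence, changed by -4.05 ± 0.17 and the transcription factor WRKY70 (AT3G56400) by -3.48 ± 0.13. Of 17 aquaporins 14 fell and 2 rose (median -2.69, adjusted p = 9.62e-06, and adjusted p = 0.0132 with an estimated correlation), among them the plasma membrane channel PIP1;5 (AT4G23400) at -4.38 ± 0.12 and the vacuolar channel TIP2 (AT3G26520) at -4.24 ± 0.12. In the cell wall list 8 of 11 genes fell and 1 rose (median -3.01, adjusted p = 0.00279, and adjusted p = 0.0899 with an estimated correlation). The wall enzyme XTH24 (AT4G30270) changed by -4.96 ± 0.12, the expansin EXPA8 (AT2G40610) was at least 385-fold lower, and the glycosyl hydrolase GH9B13 (AT4G02290) at least 263-fold lower.

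Members of other lists changed in WT in drought too. Of their list tests those of the root markers and guard cell genes passed the threshold, and the others did not. Of 12 m6A readers 4 rose, with 2.61 ± 0.11 for ECT8 (AT1G79270), and 4 fell, with -2.25 ± 0.25 for ECT6 (AT3G17330). In mRNA decay 5 of 16 genes rose and 4 fell, and the deadenylases CAF1a (AT3G44260) and CAF1b (AT5G22250) changed by -4.37 ± 0.13 and -3.12 ± 0.18; the median of the list was 0.13 while its mean was -0.34. In reactive oxygen handling 7 of 15 genes rose and 7 fell, with 1.67 ± 0.09 for the dehydroascorbate reductase DHAR1 (AT1G19570) and -3.09 ± 0.10 for the oxidase RBOHD (AT5G47910). Among 16 senescence and autophagy genes 9 rose and 5 fell, with 2.52 ± 0.12 for SAG21 (AT4G02380) and -2.61 ± 0.12 for WRKY53 (AT4G23810). In the clock list 6 of 11 genes rose and 4 fell, with 1.86 ± 0.14 for ELF4 (AT2G40080) and -1.32 ± 0.16 for GI (AT1G22770). Of 33 cytosolic ribosomal protein genes 14 rose and 5 fell, or 13 and 5 adjusted over the list alone. Of 6 writers 2 rose, and of 3 erasers 1 rose. Of 6 trichome genes 4 fell, and of 7 vascular genes 2 rose and 5 fell, including the xylem protease XCP1 (AT4G35350) at -2.18 ± 0.23. Of 6 guard cell genes 5 fell (median -1.72, adjusted p = 0.0466, and adjusted p = 0.291 with an estimated correlation). That list did not pass without WT control replicate 1, WT drought replicate 3, mta control replicate 1 or mta control replicate 2 (adjusted p of 0.0719, 0.0616, 0.0575 and 0.0505). Among markers of other tissues all 3 measured root genes fell (adjusted p = 0.0315, and adjusted p = 0.136 with an estimated correlation), with -1.93 ± 0.10 for the root glucosidase PYK10 (AT3G09260). Of 3 flower and meristem genes 1 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.53, mean -0.04), and no seed marker had enough mRNA counts to be tested. The highest adjusted p among the genes named for this comparison was 3.29e-07.

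The same comparison in mta asked how drought acted on leaves with less MTA mRNA. The drought and ABA induced proteins rose and photosynthesis fell here too, while salicylate, immune and senescence genes rose. In all 12427 genes changed, 6192 upward and 6235 downward (6527 and 5651 with the span trend removed), 6514 of them at least 2-fold. Of the 21 drought and ABA induced proteins 20 rose and 1 fell (median 3.72, adjusted p = 2.24e-14, and adjusted p = 0.0302 with an estimated correlation), with 10.13 ± 0.22 for LEA7 and 9.13 ± 0.15 for the lipid transfer protein LTP4 (AT5G59310). ABA genes counted 24 risen and 5 fallen of 35 (median 0.87, adjusted p = 8.83e-05, and adjusted p = 0.0196 with an estimated correlation), with 4.52 ± 0.10 for HAI1, 3.55 ± 0.12 for the phosphatase ABI2 (AT5G57050) and an at least 117-fold higher level of HAI3. Proline and raffinose genes counted 7 risen and 2 fallen of 10 (adjusted p = 0.00815, and adjusted p = 0.129 with an estimated correlation), with P5CS1 at 3.29 ± 0.08. All 31 photosynthesis genes fell (median -2.23, adjusted p = 2.45e-24, and adjusted p = 0.0196 with an estimated correlation), with -5.11 ± 0.12 for RBCS2B and -4.63 ± 0.11 for LHCB2.3. All 16 senescence and autophagy genes rose (median 1.43, adjusted p = 1.36e-09, and adjusted p = 0.00567 with an estimated correlation), among them SAG21 at 3.58 ± 0.13, the short-chain dehydrogenase SAG13 (AT2G29350) at 2.90 ± 0.11 and the transcription factor NAC019 (AT1G52890) at 2.73 ± 0.11. Of 21 salicylate and immune genes 13 rose and 2 fell (median 0.96, adjusted p = 8.83e-05, and adjusted p = 0.0317 with an estimated correlation), with 3.80 ± 0.12 for CYP71A13 (AT2G30770), an enzyme of camalexin synthesis, and 3.37 ± 0.15 for FMO1 (AT1G19250), an enzyme of systemic acquired resistance.

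Jasmonate genes in mta counted 3 risen and 8 fallen of 13, with 3.08 ± 0.10 for the storage protein VSP2 (AT5G24770), -4.25 ± 0.13 for LOX2 and -3.91 ± 0.13 for PDF1.2. Of 17 aquaporins 13 fell and 2 rose, or 14 and 2 adjusted over the list alone (median -1.49, adjusted p = 6.46e-05, and adjusted p = 0.0313 with an estimated correlation), with PIP1;5 at -3.20 ± 0.11. Of 11 cell wall genes 10 fell and 1 rose (adjusted p = 6.84e-05, and adjusted p = 0.0302 with an estimated correlation), with -6.02 ± 0.22 for XTH7 (AT4G37800). The heat shock list held 11 risen and 5 fallen genes of 17 without passing its list test (adjusted p = 0.124), and HSP21 was at least 51.0-fold higher. In the clock list GI changed by -3.19 ± 0.20 and ELF4 by 2.19 ± 0.13. Of 16 mRNA decay genes 10 fell and 1 rose, with -1.66 ± 0.11 for CAF1a and -1.36 ± 0.18 for the decapping scaffold VCS (AT3G13300), though 4 fell and 4 rose once the trend of each library along the gene span was removed. The alternative oxidase AOX1A (AT3G22370) rose by 1.86 ± 0.12, the reader ECT8 by 1.68 ± 0.10, and SAG29 (AT5G13170), a sugar transporter of senescing leaves, by 9.94 ± 0.21. The highest adjusted p among the genes named for this comparison was 9.5e-07.

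Whether the genotypes differed in their drought response was tested as the difference of the drought effects. The rise of ABA-induced transcripts was smaller in mta, though not past the threshold with an estimated correlation (adjusted p = 0.205), and immune, senescence, jasmonate and aquaporin transcripts were shifted upward in mta relative to WT. The difference passed the threshold for 6650 genes, 3469 upward and 3181 downward. In 2248 of them the drought effect was smaller in mta, in 1633 larger, and in 2769 the fitted effects had opposite signs, whether or not they passed. Over all genes 383 passed as risen in WT and fallen in mta, and 551 as fallen in WT and risen in mta. Across all 17666 genes the 2 drought effects correlated with Pearson's r of 0.825 and Spearman's rho of 0.740, where genes are not independent replicates. Of 21 immune genes 20 had a positive difference (median 2.19, adjusted p = 5.46e-17, and adjusted p = 0.00243 with an estimated correlation), with 4.12 ± 0.20 for PAD4, 4.23 ± 0.58 for NIMIN1 (AT1G02450), which binds the salicylate receptor NPR1, and 3.64 ± 0.47 for the pyrophosphatase NUDT6 (AT2G04450). Of 16 senescence genes 14 were positive and 1 negative, or 15 and 1 adjusted over the list alone (median 1.05, adjusted p = 1.26e-09, and adjusted p = 0.00304 with an estimated correlation), with 3.73 ± 0.44 for the protease SAG12 (AT5G45890) and 3.55 ± 0.15 for WRKY53. All 13 jasmonate genes were positive (median 1.32, adjusted p = 9.52e-10, and adjusted p = 0.00304 with an estimated correlation), with 3.47 ± 0.15 for VSP1 (AT5G24780) and 2.69 ± 0.23 for the repressor JAZ5 (AT1G17380). Of 17 aquaporins 13 were positive and 3 negative (median 1.00, adjusted p = 0.000646, and adjusted p = 0.0458 with an estimated correlation), with TIP2 at 1.80 ± 0.15.

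Negative differences prevailed in other lists. Of 21 drought and ABA induced proteins 14 were negative and 4 positive (median -0.65, adjusted p = 0.00017, and adjusted p = 0.205 with an estimated correlation), with -3.28 ± 0.22 for LTI65, -2.56 ± 0.43 for LEA7 and -2.14 ± 0.11 for LTI78 (AT5G52310), also known as RD29A. Of 10 proline and raffinose genes 8 were negative and 1 positive (median -0.94, adjusted p = 0.000113, and adjusted p = 0.0633 with an estimated correlation), with P5CS2 at -1.93 ± 0.11 and P5CS1 at -1.41 ± 0.11. Of 17 heat shock genes 8 were negative and 1 positive (adjusted p = 0.0124, and adjusted p = 0.0948 with an estimated correlation), with -2.57 ± 0.19 for HSP70 (AT3G12580) and -1.42 ± 0.11 for HSC70-1 (AT5G02500). Of 11 clock genes 7 were negative and 1 positive (adjusted p = 0.00612, and adjusted p = 0.131 with an estimated correlation), with GI at -1.87 ± 0.27. Single genes with large positive differences were XTH24 at 3.85 ± 0.15, PYL4 at 3.20 ± 0.41, CAF1b at 3.14 ± 0.23 and CAF1a at 2.71 ± 0.17. The mta drought mRNA libraries carried a trend along the gene span (rank correlation of the difference with span -0.333 over genes, median difference 0.32 in the shortest and -0.47 in the longest 20% of genes). With the span trend of each library removed, 5981 genes passed and 4948 of the 6650 kept their call and direction, while the m6A readers (median -0.46 on voom values, adjusted p = 0.0236, and adjusted p = 0.205 with an estimated correlation) had a median of -0.39 and an adjusted p of 0.118.

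**Figure D1:**
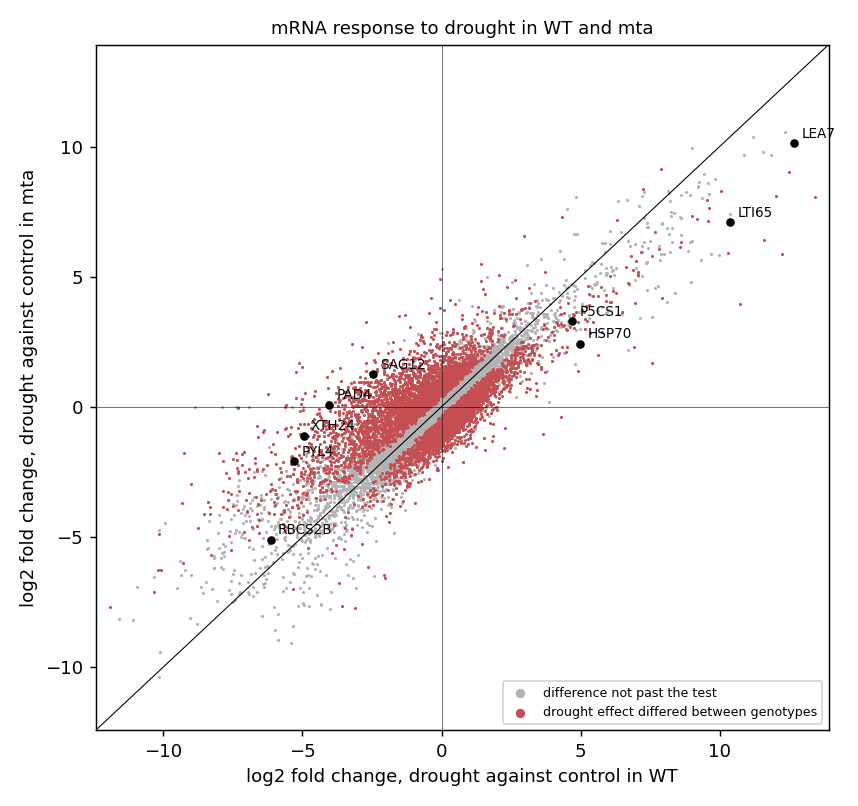
Each point is 1 gene, with its log2 fold change of mRNA between drought and control in WT on the horizontal axis and in mta on the vertical axis, fitted from 3 libraries per group. LTI65 and LEA7 lie below the line of equal change, with differences of -3.28 and -2.56, and PAD4, XTH24 and PYL4 lie above it, with differences of 4.12, 3.85 and 3.20.

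**Figure D2:**
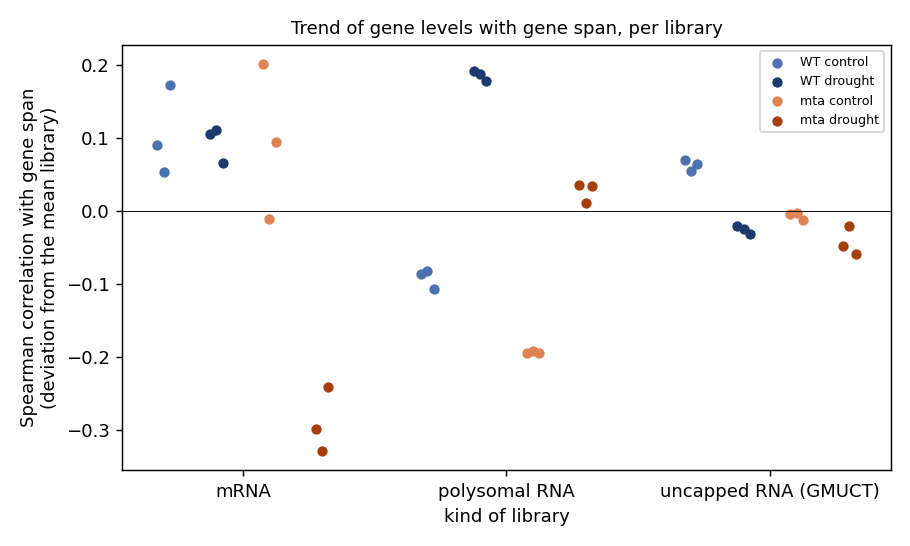
Each point is 1 library, with the rank correlation over genes between gene span and the gene's level relative to the mean library on the vertical axis, set out by assay and coloured by group. The 3 mta drought mRNA libraries lie between -0.328 and -0.241 and the other mRNA libraries between -0.0102 and 0.202.

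How mta differed from WT without drought was asked next. Some immune, heat shock and photosynthesis genes were higher in mta, but these lists failed with an estimated correlation. In all 3142 genes changed, 1502 upward and 1640 downward (1734 and 1583 without a low-count filter), and 827 of them at least 2-fold. Of 21 salicylate and immune genes 14 rose and 3 fell, or 14 and 4 adjusted over the list alone (median 1.04, adjusted p = 2.25e-06, and adjusted p = 0.0652 with an estimated correlation). Among them were the salicylate marker PR1 (AT2G14610) at 2.64 ± 0.13, the glucanase BGL2 (AT3G57260), also known as PR2, at 2.94 ± 0.09 and PR5 (AT1G75040) at 2.81 ± 0.09. Of 17 heat shock genes 8 rose and 1 fell (median 0.91, or 0.75 with genes without counts in a group at their bound, adjusted p = 9.42e-06, and adjusted p = 0.130 with an estimated correlation), with 3.40 ± 0.18 for the endoplasmic reticulum chaperone BIP3 (AT1G09080) and 2.1 ± 0.33 for HSP18.2 (AT5G59720). Of 31 photosynthesis genes 10 rose and 0 fell, or 13 and 0 adjusted over the list alone (median 0.15, adjusted p = 2.5e-06, and adjusted p = 0.169 with an estimated correlation), with LHCB3 (AT5G54270) at 0.49 ± 0.09, GAPA (AT3G26650) at 0.46 ± 0.08 and CAB1 (AT1G29930) at 0.45 ± 0.09. Of 10 proline and raffinose genes 4 rose, or 5 with 1 fallen adjusted over the list alone (adjusted p = 0.0134, and adjusted p = 0.169 with an estimated correlation), with the galactinol synthase GolS1 (AT2G47180) at 1.62 ± 0.11. Of 11 cell wall genes 3 fell, or 5 adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.169 with an estimated correlation), with TCH4 (AT5G57560) at -1.27 ± 0.10.

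Among the ABA genes 3 of 35 rose and 3 fell in mta without drought. The ABA importer ABCG40 (AT1G15520) rose by 2.2 ± 0.19 and BGLU18 (AT1G52400), which frees ABA from its glucose ester, by 1.50 ± 0.08, and CYP707A3 (AT5G45340), which breaks ABA down, changed by -2.03 ± 0.10. Drought and ABA induced proteins were divided, since of 21 measured 8 rose and 5 fell, or 9 and 6 adjusted over the list alone, with LTP4 at -1.70 ± 0.22. SAG13 and SAG12 rose by 2.58 ± 0.12 and 2.04 ± 0.22, LOX2 by 1.24 ± 0.12, and the oxidase RBOH F (AT1G64060) by 1.33 ± 0.15, while RBOHD changed by -0.85 ± 0.09. The m6A reader ECT2 (AT3G13460) rose by 0.48 ± 0.11, the 1 reader of 12 to pass. Outside the lists, among genes that met the naming rule with more than 3 counts in each group compared, the largest falls were -7.85 ± 0.20 for AT3G01345 and -5.47 ± 0.33 for AT5G37940, and the largest rise 4.02 ± 0.50 for AT1G32950. Of 11 clock genes 0 passed the edgeR test. In the flower and meristem list 2 of 3 genes fell, with -1.20 ± 0.17 for the meristem gene STM (AT1G62360), and its list test (adjusted p = 0.0245, and adjusted p = 0.169 with an estimated correlation) ended without WT control replicate 2 (adjusted p = 0.0586). The highest adjusted p among the genes named for this comparison was 0.00428.

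In drought the genotypes differed in 9308 genes, 4702 higher and 4606 lower in mta (4183 and 4732 with the span trend removed), and 3614 of them at least 2-fold. Immune, senescence and jasmonate genes stood higher in mta. Of 21 immune genes 20 were higher, or 21 adjusted over the list alone (median 3.57, adjusted p = 9.1e-18, and adjusted p = 0.00138 with an estimated correlation), with 5.18 ± 0.14 for PR1, 5.13 ± 0.09 for BGL2 and 5.16 ± 0.32 for NUDT6. Of 16 senescence genes 15 were higher and 1 lower (median 1.44, adjusted p = 1.11e-10, and adjusted p = 0.0039 with an estimated correlation), with SAG12 at 5.77 ± 0.27, SAG13 at 3.46 ± 0.11 and WRKY53 at 3.18 ± 0.12. All 13 jasmonate genes were higher (median 1.64, adjusted p = 3.19e-08, and adjusted p = 0.0039 with an estimated correlation), with VSP1 at 3.50 ± 0.11, VSP2 at 2.63 ± 0.10 and the thionin THI2.1 (AT1G72260) at 2.64 ± 0.22. Lower in mta were 16 of 21 drought and ABA induced proteins, and 3 were higher (median -0.70, adjusted p = 4.77e-08, and adjusted p = 0.113 with an estimated correlation), with LTI65 at -2.02 ± 0.10, LTI78 at -2.00 ± 0.08 and COR15B (AT2G42530), which protects membranes in the cold, at 1.79 ± 0.19. Of 10 proline and raffinose genes 7 were lower and 2 higher, or 7 and 3 adjusted over the list alone (median -0.64, adjusted p = 0.00699, and adjusted p = 0.146 with an estimated correlation), with P5CS2 at -1.37 ± 0.08. Of 11 clock genes 7 were lower and 2 higher (median -0.59, adjusted p = 0.0104, and adjusted p = 0.165 with an estimated correlation), with GI at -2.05 ± 0.22.

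The ABA list went both ways between genotypes in drought, with 9 of 35 genes higher and 17 lower (median -0.19, mean 0.05), among them PYL4 at 2.90 ± 0.38, ABCG40 at 2.71 ± 0.19 and BGLU18 at 2.55 ± 0.08. XTH24 stood at 3.61 ± 0.12, RBOH F at 1.75 ± 0.13, the reader ECT8 at -0.91 ± 0.10, and the ribosomal protein gene AT3G09630 at -0.92 ± 0.10. Photosynthesis genes, 21 of 31 higher and 7 lower (adjusted p = 0.000908, and adjusted p = 0.296 with an estimated correlation), included LHCB3 at 1.48 ± 0.09 and PSBQ-2 (AT4G05180) at 1.34 ± 0.10. Aquaporins, 11 of 17 higher and 2 lower (adjusted p = 0.0367, and adjusted p = 0.165 with an estimated correlation), included TIP2 at 1.78 ± 0.11. Both list calls ended with the span trend removed (adjusted p of 0.271 for photosynthesis and 0.242 for aquaporins, with medians on voom values of 0.12 against 0.47 and 0.45 against 0.70), and the rank correlation of this contrast with gene span was -0.360 over genes. Of 16 mRNA decay genes 11 were lower and 3 higher, with CAF1b at 2.49 ± 0.18, CAF1a at 2.15 ± 0.14 and VCS at -1.01 ± 0.18, and with the span trend removed 7 were lower. Among genes that met the naming rule outside the lists, with more than 3 counts in each group compared, the largest rise was 8.18 ± 0.18 for the cadmium resistance gene PCR1 (AT1G14880) and the largest falls were -7.57 ± 0.23 for AT3G01345 and -4.67 ± 0.21 for AT1G64795. The highest adjusted p among the genes named for this comparison was 8.33e-05.

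**Figure D3:**
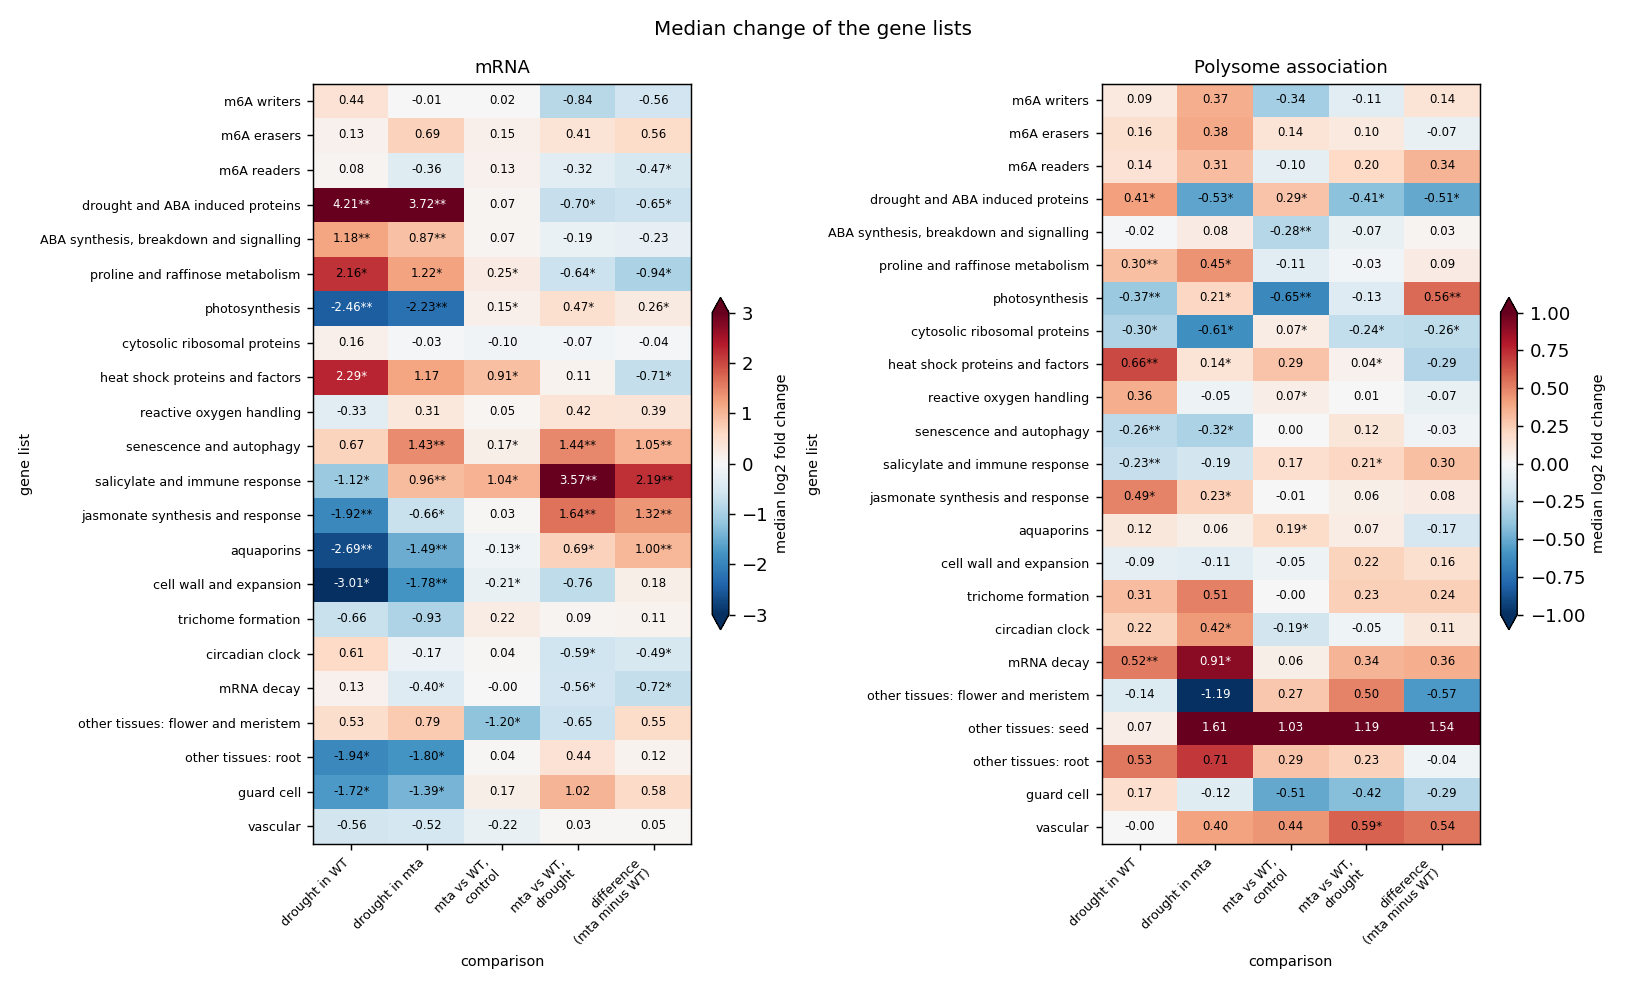
The colour gives the median log2 fold change of each fixed gene list in the 5 contrasts, for mRNA and for polysome association; 1 star marks a list test with an adjusted p under 0.05 and a pair of stars a test that also passes with an estimated correlation. The mRNA medians of the salicylate and immune list were -1.12 in WT drought, 0.96 in mta drought and 3.57 between genotypes in drought, and the polysome association of photosynthesis in control was -0.65.

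Noncoding RNAs were counted in the same mRNA libraries, and 337 were tested. Drought changed 109 in WT (72 rose, 37 fell) and 126 in mta (93 rose, 33 fell), and AT1G05347 rose by 5.60 ± 0.50 in WT and by 3.90 ± 0.43 in mta. Between genotypes 46 differed in drought (33 higher in mta, 13 lower) and 4 in control (3 higher, 1 lower), where 53 had an unadjusted p under 0.05. AT3G15536 was higher in mta by 2.89 ± 0.23 in control and 5.87 ± 0.28 in drought. The plastid transcript ATCG00090 stood at -3.66 ± 0.50 in drought, and in control at -2.80 ± 0.48 with an adjusted p of 0.00984, which became 0.237 in a fit of the compared groups alone. The control count was 23 without a low-count filter and 17 with DESeq2. It was 8 without WT control replicate 2, 36 without WT control replicate 3, 7 without mta control replicate 1 and 10 without mta control replicate 3, and the drought count was 79 without WT control replicate 3.

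The m6A libraries asked where transcripts were methylated and which regions were absent in mta. Of the WT regions, 12.2% in control and 19.5% in drought had no peak in any mta library, and peaks before the midpoint of the gene span made up a larger share in mta. There were 10741 regions in 9844 genes in WT control, 11632 in 10348 genes in WT drought, 10207 in 8579 genes in mta control and 8712 in 7753 genes in mta drought. In control 1306 WT regions lacked an mta peak and 1259 mta regions lacked a WT peak, and in drought these counts were 2271 and 416. With the same number of peaks (7746) from every library they were 1081 and 1149 in control, and 980 and 859 in drought. The WT regions without an mta peak lay in the last 10% of the span in 64.4% of cases in control and 61.8% in drought, and those shared with mta in 62.5% and 59.7%. Before the midpoint lay 1.83% and 5.80% of the WT regions without an mta peak and 8.07% and 8.57% of those shared. The mta regions without a WT peak lay before the midpoint in 64.4% of cases in control and 61.7% in drought. Per library, summits before the midpoint made up 5.61% to 10.4% in WT and 13.4% to 22.5% in mta, a difference of means of 8.69 percentage points, larger than the spread between libraries (exact permutation of genotype within each watering regime, two-sided p = 0.005, the smallest it can give).

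**Figure D4:**
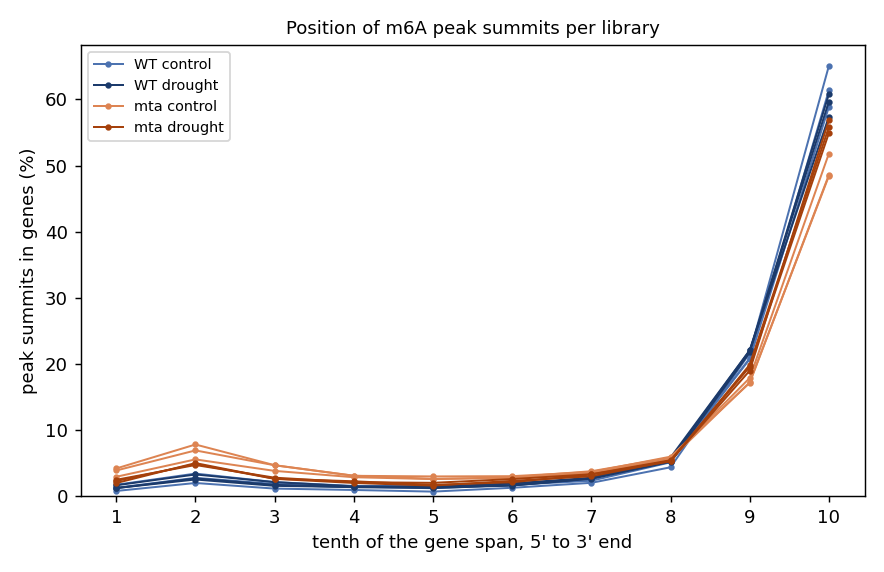
The share of m6A peak summits in percent is drawn against their position along the gene span, split into 10 equal parts from start to end, with 1 line per library of WT and mta. The last part holds 57.4% to 65.1% of the summits in WT libraries and 48.4% to 56.9% in mta libraries.

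The MTA transcript itself held a WT region absent in mta in both regimes, on chromosome 4 from 6619830 to 6620034 in control (mean fold enrichment 6.73) and from 6619827 to 6620028 in drought (5.29), while its mRNA counts were lower there too. The regions of control with the highest fold in all 3 WT libraries and no mta peak lay in AT5G05800 (chromosome 5, 1743120 to 1743263, fold 9.93), AT1G49850 (8.96), the transcription factor WRKY4 (chromosome 1, 4779071 to 4779259, 8.94), the flagellin receptor FLS2 (chromosome 5, 18795363 to 18795516, 8.74) and MYB33 (chromosome 5, 1840510 to 1840658, 8.58). In drought they lay in AT2G31170, a cysteinyl-tRNA synthetase (chromosome 2, 13282403 to 13282710, fold 12.0), the methionine aminopeptidase MAP1B (chromosome 3, 9399577 to 9399685, 11.8), AT5G63080, AT5G38290 and AT1G75420. Of all genes with a WT region 1134 of 9844 lost every one in control and 1796 of 10348 in drought. Equal peak numbers gave 1029 and 874, and the lists were not tested against these. Of 11 m6A readers with a WT region in control 4 lost every region, and of 7 in drought 0 did. Of 28 ribosomal protein genes with a region in control 7 lost it, and of 30 in drought 4. In drought 7 of 14 photosynthesis, 4 of 8 reactive oxygen and 2 of 4 proline and raffinose genes lost theirs. NYE1 (AT4G22920) and ACD1 (AT3G44880), enzymes of chlorophyll breakdown, lost their regions in both regimes, as did NPR1. No clock gene (of 10 in control and 9 in drought) and no mRNA decay gene (of 14 in each) lost every region. Without mta control replicate 3 the control count of 1306 was 2348 (reverse count 635), and it was 470 without WT control replicate 1 (reverse 1725) and 423 without WT control replicate 2 (reverse 1604).

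In WT 1043 drought regions had no control peak (8.97%) and 677 control regions had no drought peak, and with the same number of peaks 646 and 651. In mta these counts were 428 (4.91%) and 1579, and with the same number of peaks 752 and 956. The WT count was 691 without WT drought replicate 1, 650 without WT drought replicate 3 and 1630 without WT control replicate 2. The mta count was 232 without mta drought replicate 1, 183 without mta drought replicate 3 and 944 without mta control replicate 3.

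Genes that lost every m6A region in mta were then set against genes that kept one, to ask whether their mRNA, uncapped share or polysome association moved. None of the 6 tests passed 0.05. The median difference between lost and kept genes in mRNA was 0.04 in control (adjusted p over the 6 tests = 0.698) and -0.05 in drought, where the test pointed upward while median and mean were negative. In the uncapped share it was -0.0022 in control and 0.03 in drought, and in polysome association -0.04 and 0.04, and these 5 tests had an adjusted p of 0.903. Without WT control replicate 1 the control difference in mRNA was 0.06 and passed 0.05 unadjusted.

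GMUCT against mRNA asked how the uncapped share of each transcript moved. In WT drought changed it for 877 of 19142 genes, 560 upward and 317 downward, and 447 at least 2-fold. P5CS1, which rose in mRNA, had a lower uncapped share, at -1.0 ± 0.14. EDS1 (AT3G48090), a partner of PAD4, rose by 1.15 ± 0.19 and the photosystem subunit PSAD-1 (AT4G02770) by 0.78 ± 0.14. The division into rises and falls turned with the set of genes used, to 457 and 1264 without a low-count filter and 453 and 935 with nuclear genes alone, which moved the median of all genes by -0.20 and -0.14. With median-of-ratios scaling it was 564 and 340. The count was 405 without WT drought replicate 3, 433 without WT control replicate 2, 446 without WT drought replicate 2 and 478 without WT control replicate 1.

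In mta drought changed the uncapped share of 3648 genes, 1995 upward and 1653 downward, and 1389 at least 2-fold. The exonuclease XRN4 (AT1G54490), which degrades decapped mRNA, had a higher share by 1.53 ± 0.17, LOX2 by 2.13 ± 0.20, EDS1 by 1.61 ± 0.16, the cellulose synthase CESA1 (AT4G32410) by 1.26 ± 0.18, the catalase CAT2 (AT4G35090) by 1.13 ± 0.18 and Rubisco activase RCA (AT2G39730) by 1.05 ± 0.14. LEA7 stood at -1.70 ± 0.38, SAG21 at -1.11 ± 0.19 and the ribosomal protein RPL23AA (AT2G39460) at -1.10 ± 0.18. Of 33 ribosomal protein genes 18 fell, or 20 adjusted over the list alone (median -0.59, adjusted p = 2.07e-07, and adjusted p = 0.253 with an estimated correlation). Of 21 drought and ABA induced proteins 10 fell and 1 rose, or 13 and 1 adjusted over the list alone (adjusted p = 0.00472, and adjusted p = 0.253 with an estimated correlation). In mRNA decay 6 of 16 genes rose, or 8 adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.253 with an estimated correlation). The span trend of the mta drought mRNA libraries enters this measure (rank correlation with span 0.357 over genes). With it removed 2275 genes passed, 6 ribosomal genes fell, and the calls of the drought and ABA and mRNA decay lists ended (adjusted p of 0.0957 and 0.446, with medians on voom values of -0.16 against -0.43 and 0.07 against 0.51). The set of genes turned the division here too, to 1439 and 2801 without a filter and 1628 and 2538 with nuclear genes (medians moved by -0.17 and -0.11), while median-of-ratios scaling gave 2097 and 1588. The count was 1969 without mta drought replicate 2.

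Between genotypes the uncapped share differed for 67 genes in control, 32 higher and 35 lower in mta, or 41 and 32 with median-of-ratios scaling, 50 and 34 with nuclear genes and 60 and 47 with the span trend removed. The nucleoside transporter ENT6 (AT4G05110) stood at 4.52 ± 0.54, DRL1 (AT4G35420) at 2.16 ± 0.35, the replication protein PRL (AT4G02060) at 2.01 ± 0.31 and the transcription factor NTL9 (AT4G35580) at -1.41 ± 0.22. The photosynthesis list had a median of -0.28 with 0 of 31 members past edgeR's test, 1 risen and 6 fallen adjusted over the list alone (adjusted p = 3.31e-07, and adjusted p = 0.187 with an estimated correlation). The 1 measured seed marker had a log2 fold change of 6.09 and did not pass the gene test. The count was 15 without WT control replicate 2, 20 without WT control replicate 1, 20 without mta control replicate 3, 22 without mta control replicate 2 and 43 without WT drought replicate 2, and it was 187 without a filter (117 higher, 70 lower), 218 with DESeq2 and 666 with voom.

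In drought the uncapped share differed between genotypes for 3151 genes, 1375 higher and 1776 lower in mta, and 1219 at least 2-fold. The division turned to 1610 and 1570 with median-of-ratios scaling, 1558 and 1515 without a filter, 1702 and 1507 with nuclear genes and 868 and 848 with the span trend removed. XRN4 stood at 1.42 ± 0.18, LOX2 at 1.64 ± 0.21, CESA1 at 1.39 ± 0.18, RCA at 0.99 ± 0.14, HSP70 at 0.96 ± 0.17 and P5CS1 at 0.83 ± 0.13. The cold-induced proteins KIN1 (AT5G15960) and KIN2 (AT5G15970) stood at -1.06 ± 0.19 and -1.23 ± 0.19, and WRKY70 at -0.97 ± 0.21. Of 33 ribosomal protein genes 14 were lower (adjusted p = 0.00018, and adjusted p = 0.391 with an estimated correlation), and of 16 mRNA decay genes 8 were higher and 2 lower, or 9 and 3 adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.204 with an estimated correlation). The rank correlation with gene span was 0.395 over genes, and with the span trend removed 1716 genes passed and both list calls ended (adjusted p of 0.591 and 0.523, with medians on voom values of -0.0033 against -0.39 and 0.11 against 0.59). The count was 1794 without mta drought replicate 2 and 2004 without WT drought replicate 2.

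The difference of the drought effects on the uncapped share passed for 1373 genes, 726 positive and 647 negative. Positive were LOX2 at 1.72 ± 0.29, XRN4 at 1.52 ± 0.25, RCA at 1.3 ± 0.19 and the catalase CAT3 (AT1G20620) at 1.18 ± 0.20, and negative were the dehydrin LTI30 (AT3G50970) at -1.66 ± 0.29 and KIN2 at -1.46 ± 0.27. With the span trend removed 428 passed, of which 350 were shared with the 1373. The count was 573 without WT control replicate 2, 575 without mta drought replicate 2, 663 without WT drought replicate 2, 709 without WT control replicate 1, 783 without WT drought replicate 3 and 911 without mta drought replicate 1.

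Polysomal RNA against mRNA asked how transcripts were loaded onto ribosomes. In WT drought moved photosynthesis transcripts away from polysomes and 6 of 18 heat shock genes toward them. Of 20392 genes 3828 changed, 2415 upward and 1413 downward, and 864 at least 2-fold. Of 31 photosynthesis genes 22 fell, or 23 adjusted over the list alone (median -0.37, adjusted p = 5.15e-21, and adjusted p = 0.0205 with an estimated correlation), with PSBQ-2 at -0.99 ± 0.10 and GAPA at -0.76 ± 0.08. Of 33 ribosomal protein genes 18 fell, or 19 with 1 risen adjusted over the list alone (median -0.30, adjusted p = 2.38e-07, and adjusted p = 0.208 with an estimated correlation), with AT1G34030 at -0.71 ± 0.14. Of 18 heat shock genes 6 rose (adjusted p = 4.74e-05, and adjusted p = 0.00446 with an estimated correlation), with HSP70 at 1.31 ± 0.15. Senescence genes fell in 7 of 16 cases, or 8 adjusted over the list alone (adjusted p = 0.000143, and adjusted p = 0.00446 with an estimated correlation), with SAG13 at -1.26 ± 0.12. Immune genes fell in 5 of 21 cases (6 adjusted over the list alone, adjusted p = 0.0083, and adjusted p = 0.0361 with an estimated correlation), with PR5 at -0.83 ± 0.09. Of 21 drought and ABA induced proteins 11 rose and 4 fell, or 11 and 5 adjusted over the list alone (median 0.41, adjusted p = 0.00215, and adjusted p = 0.277 with an estimated correlation), and the list did not pass without mta control replicate 1 (adjusted p = 0.0545). LEA7 rose by 3.33 ± 0.73, LTI65 by 3.00 ± 0.37, LTI78 by 0.97 ± 0.08, the ABA synthesis enzyme NCED3 (AT3G14440) by 1.17 ± 0.14 and GolS1 by 1.34 ± 0.15, while the superoxide dismutase FSD1 (AT4G25100) stood at -1.0 ± 0.10. The rank correlation with gene span was 0.308 (0.165 in the polysomal libraries alone). Median-of-ratios scaling gave 1751 rises and 2065 falls, and removal of the span trend 1170 and 1413.

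In mta drought changed the polysome association of 7267 genes, 4412 upward and 2855 downward, and 2408 at least 2-fold. RCA rose by 1.54 ± 0.07, LOX2 by 2.44 ± 0.14, VSP1 by 1.65 ± 0.11, the chaperones HSP101 (AT1G74310) and HSC70-1 by 2.39 ± 0.29 and 1.76 ± 0.08, NCED3 by 2.07 ± 0.15, P5CS1 by 1.09 ± 0.07, LTI78 by 1.28 ± 0.08 and the reader ECT2 by 1.38 ± 0.13. LEA7 stood at -1.77 ± 0.27. Of 33 ribosomal protein genes 25 fell and 1 rose, or 25 and 2 adjusted over the list alone (median -0.61, adjusted p = 1.42e-12, and adjusted p = 0.0654 with an estimated correlation), with AT1G34030 at -1.02 ± 0.14. Proline and raffinose genes rose in 5 of 10 cases, or 7 adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.0596 with an estimated correlation). The rank correlation with gene span was 0.519 over genes, and with the span trend removed 4716 genes passed, of which 3488 kept their call and direction and 124 turned. Median-of-ratios scaling gave 3756 rises and 3773 falls.

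Between genotypes in control the polysome association of photosynthesis transcripts was lower in mta, in 30 of 31 genes (median -0.65, adjusted p = 1.4e-88, and adjusted p = 6.08e-05 with an estimated correlation). LHCB3 stood at -1.14 ± 0.09, GAPA at -1.13 ± 0.08 and the chlorophyll binding protein CAB3 (AT1G29910) at -1.08 ± 0.11, and in the polysomal libraries taken alone 27 of the 31 genes were lower and 1 higher (median -0.43). In all 1684 genes differed, 483 upward and 1201 downward, 204 of them at least 2-fold. Of 37 ABA genes 8 were lower, or 12 with 1 higher adjusted over the list alone (median -0.28, adjusted p = 0.0164, and adjusted p = 0.0486 with an estimated correlation), with the zeaxanthin epoxidase ABA1 (AT5G67030) at -0.67 ± 0.09. Of 11 clock genes 4 were lower, or 5 adjusted over the list alone (adjusted p = 0.00362, and adjusted p = 0.104 with an estimated correlation), with LHY (AT1G01060) at -0.94 ± 0.11, TOC1 (AT5G61380) at -0.86 ± 0.11 and CCA1 (AT2G46830) at -0.66 ± 0.12. P5CS2 stood at -1.13 ± 0.09, P5CS1 at -0.76 ± 0.07 and ECT2 at -0.71 ± 0.13. Of 21 drought and ABA induced proteins 9 were higher and 1 lower, or 10 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.000208, and adjusted p = 0.248 with an estimated correlation), with LEA7 at 4.57 ± 0.81 and LTI65 at 2.61 ± 0.38. Of 17 aquaporins 2 were higher, or 5 adjusted over the list alone (adjusted p = 6.79e-05, and adjusted p = 0.157 with an estimated correlation), with GAMMA-TIP (AT2G36830) at 0.67 ± 0.12. The lipid transfer protein AZI1 (AT4G12470) of systemic immunity stood at 1.57 ± 0.20. The count was 957 without mta control replicate 3, 978 without WT control replicate 1, 1101 without WT control replicate 2 and 2989 with voom, and median-of-ratios scaling gave 605 higher and 828 lower.

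**Figure D5:**
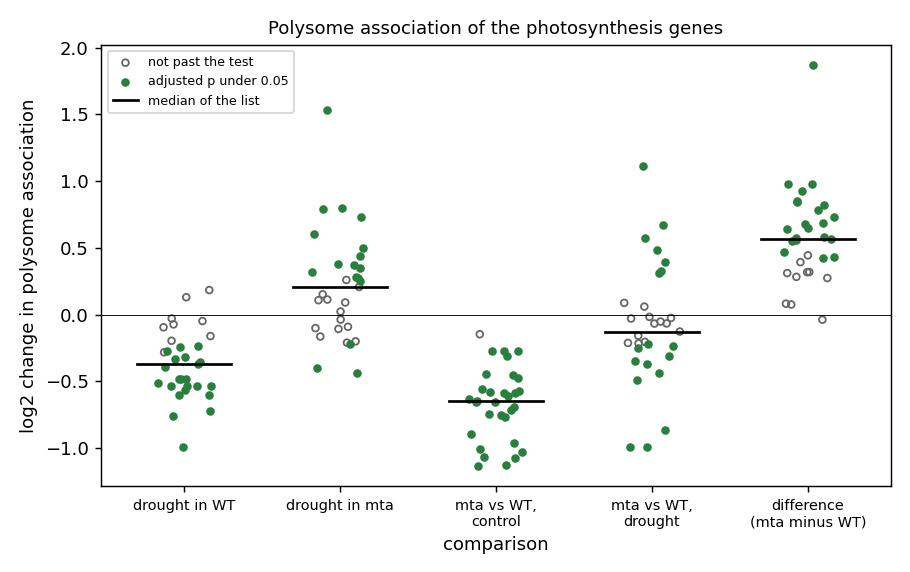
Each point is 1 photosynthesis gene, with its log2 fold change of polysome association on the vertical axis for each contrast and the median as a bar. Between genotypes in control 30 of 31 genes were lower in mta with a median of -0.65, and the difference of the drought effects had a median of 0.56.

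In drought 3416 genes differed between genotypes in polysome association, 1779 higher and 1637 lower in mta, and 529 at least 2-fold. ABCG40 stood at 3.14 ± 0.23, FRK1 (AT2G19190), a kinase induced by flagellin, at 1.97 ± 0.31, LOX2 at 1.53 ± 0.15, BGLU18 at 1.38 ± 0.08, the xylem protease XCP2 (AT1G20850) at 1.22 ± 0.19, RCA at 1.12 ± 0.07 and EDS1 at 0.82 ± 0.17. Lower were CAF1a at -1.52 ± 0.15, CAB3 at -0.99 ± 0.11, RAB18 at -0.67 ± 0.09 and LTI30 at -0.65 ± 0.12. In the list of drought and ABA induced proteins 12 of 21 were lower and 3 higher, or 13 and 3 adjusted over the list alone (median -0.41, adjusted p = 4.59e-08, and adjusted p = 0.095 with an estimated correlation). Among 7 vascular genes 4 were higher, or 5 adjusted over the list alone (adjusted p = 0.00293, and adjusted p = 0.095 with an estimated correlation). Photosynthesis genes were split, 7 of 31 higher and 11 lower. The rank correlation with gene span was 0.280 over genes, and with the span trend removed 2475 genes passed, 2099 of them with the same call. The count was 2127 without mta drought replicate 2 and 2148 without mta drought replicate 1.

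The drought effect on polysome association differed between genotypes for 1955 genes, 1385 positive and 570 negative, and 649 at least 2-fold. Of 31 photosynthesis genes 21 were positive, or 27 adjusted over the list alone (median 0.56, adjusted p = 4.3e-31, and adjusted p = 0.0127 with an estimated correlation), with RCA at 1.87 ± 0.10 and GAPB (AT1G42970) and LHCB4.1 (AT5G01530) each at 0.98 with SE of 0.12 and 0.11. Negative were 10 of 21 drought and ABA induced proteins, or 11 with 2 positive adjusted over the list alone (median -0.51, adjusted p = 1.4e-08, and adjusted p = 0.146 with an estimated correlation), with LEA7 at -5.10 ± 0.84 and LTI65 at -2.35 ± 0.41. ABCG40 stood at 2.88 ± 0.31, BGLU18 at 1.24 ± 0.12, P5CS1 at 1.11 ± 0.10 and CAF1a at -1.59 ± 0.18. The count was 1272 without WT control replicate 2 and 1303 without mta drought replicate 1, and 1234 with the span trend removed, of which 1020 were shared with the 1955.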

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

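The splits of the samples, the removal of the span trend, the left-out list tests and the tests of explanations in the last 3 paragraphs were chosen after the results were seen. The results of the first 3 paragraphs stand out because the drought effect differed between the 2 genotypes by a test of that difference. The difference passed for 6650 genes in mRNA, 1373 in the uncapped share and 1955 in polysome association. In mRNA 2 of 40 splits of the samples, the real one included, gave as many genes, with 7983 as the highest other count. In the uncapped share 1 of 40 did, the real one, with 698 as the highest other, and in polysome association 3 of 40 did, with 2229 as the highest other. Such splits shuffle the genotype labels within each watering regime and assay separately. They can leave a real genotype difference within a regime in place, as the 1 other split as large in mRNA and the 2 in polysome association did. They therefore say nothing about chance.

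In mRNA the median differences of the lists, mta minus WT, were 2.19 for the salicylate and immune genes, 1.32 for jasmonate, 1.05 for senescence and autophagy, 1.00 for aquaporins, 0.26 for photosynthesis, -0.47 for m6A readers, -0.49 for the clock, -0.65 for drought and ABA induced proteins, -0.71 for heat shock, -0.72 for mRNA decay and -0.94 for proline and raffinose metabolism. With an estimated correlation the first 4 of these lists passed and the other 7 did not (adjusted p from 0.0633 to 0.493). With the span trend of each library removed photosynthesis, mRNA decay and the readers did not pass (adjusted p of 0.684, 0.817 and 0.118). On voom values the medians of photosynthesis and mRNA decay then went from 0.27 to -0.013 and from -0.73 to -0.12, while the readers stayed near their value (-0.46 and -0.39). Ribosomal proteins passed only then (-0.018 to -0.35, adjusted p = 0.000115), though not with an estimated correlation (adjusted p = 0.174). Photosynthesis also did not pass without WT control replicate 1, mta drought replicate 1 or mta drought replicate 2 (adjusted p of 0.0695, 0.0518 and 0.0665), nor did mRNA decay without mta control replicate 1 or mta drought replicate 1 (0.0646 and 0.0542). In the uncapped share the medians were 0.58 for m6A readers, 0.63 for mRNA decay, -0.24 for drought and ABA induced proteins, -0.37 for ribosomal proteins, -0.42 for senescence and -0.54 for aquaporins, and none of these 6 list calls passed with the span trend removed (adjusted p of 0.259, 0.363, 0.649, 0.791, 0.649 and 0.363) or with an estimated correlation (0.0946 to 0.586). On voom values they went from 0.60 to 0.35, 0.63 to 0.18, -0.25 to 0.15, -0.37 to -0.00066, -0.43 to -0.062 and -0.51 to -0.30 with the trend removed. Photosynthesis passed only then (-0.026 to 0.35, adjusted p = 9.95e-07), though not with an estimated correlation (adjusted p = 0.330). Drought and ABA induced proteins did not pass without WT control replicate 2, WT drought replicate 1, mta control replicate 1, mta drought replicate 1 or mta drought replicate 2 (medians -0.15, -0.28, -0.11, -0.25 and -0.25, adjusted p of 0.117, 0.0799, 0.135, 0.0595 and 0.0758). In polysome association they were 0.56 for photosynthesis, -0.51 for drought and ABA induced proteins and -0.26 for ribosomal proteins, the last of which did not pass with the span trend removed (median on voom values from -0.29 to -0.11, adjusted p = 0.107), while immune and vascular genes passed only then (adjusted p of 0.0295 for both, and 0.106 and 0.264 with an estimated correlation). With an estimated correlation photosynthesis passed (adjusted p = 0.0127), and drought and ABA induced proteins and ribosomal proteins did not (adjusted p of 0.146 and 0.352).

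Single genes with a difference in mRNA were LTI65 (-3.28), LEA7 (-2.56), LTI78 (-2.14), P5CS2 (-1.93), P5CS1 (-1.41), HSP70 (-2.57), HSC70-1 (-1.42) and GI (-1.87) on the negative side. On the positive side were NIMIN1 (4.23), PAD4 (4.12), NUDT6 (3.64), WRKY53 (3.55), SAG12 (3.73), VSP1 (3.47), JAZ5 (2.69), XTH24 (3.85), TIP2 (1.80), PYL4 (3.20), CAF1b (3.14) and CAF1a (2.71). In the uncapped share they were XRN4 (1.52), RCA (1.3), LOX2 (1.72), CAT3 (1.18), LTI30 (-1.66) and KIN2 (-1.46). In polysome association they were LEA7 (-5.10), LTI65 (-2.35), CAF1a (-1.59), RCA (1.87), GAPB (0.98), LHCB4.1 (0.98), ABCG40 (2.88), BGLU18 (1.24) and P5CS1 (1.11).

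Long genes were lower and short genes higher in the mRNA libraries of mta in drought, with a rank correlation of the difference with gene span of -0.333 over genes. The polysomal difference correlated with span at -0.084, and its median was 0.16 in the shortest 20% of genes against 0.32 in mRNA. Between genotypes in drought these medians were 0.29 and 0.33, so the polysomal libraries shared part of the rise of short genes. A difference in fragmentation or RNA quality of the input libraries may account for the rest, and was not tested. Removal of the trend left 4948 of the mRNA calls, which argues against the trend as their whole cause. It left 1020 of the polysome association and 350 of the 1373 uncapped share calls. There the trend cannot be told apart from a genotype effect because the mRNA libraries carry both. A fall of long transcripts in the plants stays open, since the longest 20% of genes had a median polysomal difference of -0.058 against -0.47 in mRNA. In GMUCT, which reads decaying transcripts, it was 0.0085 with a rank correlation with span of 0.066, so neither of these assays showed a fall of that size. A fall in mRNA cannot be told apart from loading that made up for it.

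Photosynthesis transcripts were lower on polysomes relative to mRNA in mta without drought, with a median log2 difference of -0.65. On the voom values of the list tests the median was -0.62, and it was -0.57 with median-of-ratios scaling and -0.52 without WT control replicate 3, the shallow library with many plastid counts, which argues against scaling and against that library as the cause. A harvest of the mta plants at another time of day would move clock transcripts in mRNA, and their median absolute difference there was 0.10, with PRR9 apart at -1.23 ± 0.44 (adjusted p = 0.0546). In the polysomal libraries it was 0.37, so a harvest of the polysomal material at another time stays open, since this value lies between what it would need and what would speak against it. A lower loading of photosynthesis transcripts in mta may account for the pattern, as a hypothesis found on these data, and separate handling of the polysomal material of the 2 genotypes was not tested.

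Peaks before the midpoint of the gene span took a larger share in mta than in WT. With the same number of peaks in every library the difference was 10.0 percentage points. Keeping the strongest peaks lowered this share in each library that lost peaks, so in drought it does not decide whether peak number takes part. Control libraries held 8269 to 12228 peaks in WT and 8374 to 12145 in mta. Mean shares of 8.20% and 20.62% argue against peak number there. In control the regions without a peak in the other genotype differed in this share by 62.6 points between mta and WT. That value restates the pattern, so it does not decide whether regions near the limit of detection take part, which stays open. The count of WT drought regions without an mta peak fell from 2271 to 980, beside a reverse count of 859, once peak numbers were equal. Equal numbers draw both counts together whatever the cause, which stays open. More unspecific peaks in the mta libraries could also place summits early in the gene and stay open, because no sequence was at hand to look for the m6A motif.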

How the results depend on the processing

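The removal of the span trend, the halving of polysomal counts and the rescaled and left-out list tests were chosen after seeing the data, and the other alternatives before. Of 4430 comparisons of named genes with an alternative 4421 kept direction and side of the threshold, 9 no longer passed and 0 reversed. Most named genes were chosen for large changes in these data, which favours this. The 9 were ATCG00090 among noncoding RNAs in control (groups compared alone) and TCH4 in the uncapped share in control. TCH4 had -1.04 ± 0.23 (adjusted p = 0.0351). Its adjusted p was 0.0533 to 0.173 with any 1 control replicate, WT drought replicate 2 or mta drought replicate 2 left out. Of 473 comparisons of counts 382 stayed within 1.5 times and 91 moved further. At most 164 calls turned direction, in drought against control in mta in mRNA with the span trend removed. Where a left-out library leaves 2 in a group, the spread is pooled over groups. The cause of the shifts below was not tested, except that a minimum fold and a smaller number of samples or peaks lower counts by construction.

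With a minimum 2-fold change the counts, in the order WT drought, mta drought, genotype in control, genotype in drought, were 6787, 6514, 827 and 3614 in mRNA (difference of drought effects 3183), 447, 1389, 30 and 1219 in the uncapped share and 864, 2408, 204 and 529 in polysome association (difference 649). Without a low-count filter the uncapped share gave 1721 in WT drought and 187 in control, and noncoding RNAs 23 in control. With nuclear genes alone the uncapped share in WT drought gave 1388. With voom it gave 2208 in WT drought, 666 in control and 2263 in the difference, and polysome association 2989 in control. With DESeq2 the uncapped share gave 218 in control and noncoding RNAs 17. With the compared groups alone the uncapped share gave 35 in control, and noncoding RNAs 2 in control and 99 in drought. The replicate block gave 142 for the uncapped share in control. With the span trend removed the uncapped share gave 2275 in mta drought, 107 in control, 1716 between genotypes in drought and 428 in the difference, and polysome association 4716 in mta drought and 1234 in the difference. Of the list tests 103 passed, 29 with an estimated correlation, 179 with fry, 84 with the span trend removed (32 lost, 13 gained) and 95 to 104 with a library left out, and 0 turned direction.

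For m6A, the same number of peaks gave 7747 regions in WT drought. WT regions without an mta peak were, in control, 388 with support of all 3 libraries, 2556 with 1 library and 2215 with 0.5 of the region to be covered, (reverse counts 453, 2902 and 1797), and in drought 1352, 3551 and 3627 (reverse 141, 1219 and 586), and 980 with the same number of peaks. Drought regions without a control peak were 508, 2100, 1763 and 646 in WT and 157, 1250, 746 and 752 in mta. Among the tests of genes that lost m6A, those against all genes passed for mRNA in drought (-0.21) and polysome association in control (-0.091), and for polysome association in drought the sign reversed (-0.0037). For the uncapped share in control it reversed with support of all 3 libraries (0.0086), and without WT control replicates 1 or 3 or mta control replicates 2 or 3 (0.0071, 0.0071, 0.0089 and 0.0013).

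Leaving out 1 library in turn gave, from lowest to highest, 11103 to 12330 genes in WT drought, 11777 to 12791 in mta drought, 2158 to 3173 between genotypes in control, 8429 to 9624 in drought and 5810 to 6956 in the difference for mRNA. For noncoding RNAs the first 4 ranges were 81 to 145, 98 to 158, 3 to 36 and 31 to 79. For the uncapped share the 5 ranges were 405 to 1097, 1969 to 4157, 15 to 82, 1794 to 3439 and 573 to 1572. For polysome association they were 2824 to 4249, 6201 to 7950, 957 to 1634, 2127 to 3650 and 1272 to 2300. Regions were 7907 to 10439 in WT control, 10416 to 10822 in WT drought, 7453 to 9511 in mta control and 6831 to 8016 in mta drought. WT regions without an mta peak were 423 to 2348 in control and 1571 to 3342 in drought, and drought regions without a control peak 650 to 1630 in WT and 183 to 944 in mta. The difference of genes that lost m6A was 0.033 to 0.065 in mRNA in control (past 0.05 without WT control replicate 1), -0.057 to -0.037 in drought, -0.0078 to 0.0089 and 0.012 to 0.051 in the uncapped share, and -0.057 to -0.031 and 0.014 to 0.033 in polysome association. The simulated shares called rest on 200 changed genes and can differ with more, as in the data.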

Other observations

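The splits of samples in this part were tested after the results were seen. Clock transcripts were looked at in each assay alone, in mta against WT without drought. In the polysomal libraries taken alone LHY changed by -0.79, TOC1 by -0.90, CCA1 by -0.57, PRR7 by -0.50 and RVE8 by -0.42, and ELF4 by 0.37, while in mRNA the log2 fold changes were 0.10 ± 0.10 for LHY, -0.10 ± 0.10 for TOC1 and 0.04 ± 0.10 for CCA1. The largest mRNA change was that of PRR9, at -1.23 ± 0.44 (adjusted p = 0.0546), and 0 of 11 clock genes passed the edgeR test. In GMUCT ELF4 changed by 0.58 ± 0.14 (adjusted p = 0.00412), RVE8 by 0.51 ± 0.14 (adjusted p = 0.0121) and PRR5 by 0.65 ± 0.16 (adjusted p = 0.0042).

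Other splits of the same libraries into groups of the same sizes give a scale for the counts. For the mRNA and noncoding contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real mRNA split, 1 of the 10 to give as many, gave 12000, 12427, 3142 and 9308 genes for WT drought, mta drought, control and drought, and the highest other split 0, 0, 0 and 1. For noncoding RNAs the real counts were 109, 126, 4 and 46 and the highest others 0, 0, 37 and 0, where 2 splits reached the count in control.

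For the uncapped share 6, 3, 3 and 6 of 40 splits gave at least the 877, 3648, 67 and 3151 genes of the real ones, and the highest others gave 9431, 9296, 2641 and 6064. For polysome association 5, 3, 4 and 6 of 40 splits did, against 3828, 7267, 1684 and 3416 real and 13053, 9622, 4910 and 8029 as the highest others. The labels of the 2 assays were shuffled separately, so that such a split can set drought libraries of 1 assay against control libraries of the other. In all of the other splits with counts at least as large (5, 2, 2 and 5 for the uncapped share, 4, 2, 3 and 5 for polysome association) 1 assay kept its real division or its mirror. Counts several times the real one point to this structure of the samples, and these splits say nothing about chance. For the list tests 3 of 30 splits gave at least the 103 calls, with 113 as the highest other, and the same holds for them.

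For genes that lost m6A, the 10 splits of the mRNA libraries are too few for a share under 0.05, with 1 split each as large as the real 0.04 in control (highest other -0.02) and -0.05 in drought (highest other -0.04). For the uncapped share 92 of 100 splits were as large as -0.002 in control (highest other -0.08) and 17 as large as 0.03 in drought (highest other 0.06). For polysome association 10 of 100 were as large as -0.04 in control (highest other -0.06) and 14 as large as 0.04 in drought (highest other -0.07). These splits of 2 assays also say nothing about chance.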
